A study of Rattus norvegicus with 12 samples.

How the data were processed

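The study measured gene expression on 12 one-colour Affymetrix rat arrays. Each array held RNA of 1 pool of 2 tissues, left atrium or left ventricle, from male Sprague Dawley rats 28 days after a sham operation or an aorto-caval shunt, a surgical connection between aorta and vena cava that loads the heart with extra blood volume. Per the labels' protocols, biotin-labelled cRNA was made from 10 µg of total RNA. Per the submitters' processing notes, the deposited values are RMA values, the version of RMA is not given in the sources used here, and which arrays were normalized together is not given either. The deposited values lie on a log2 scale, from 2.05 to 14.29 with nearly equal quartiles on all arrays. No array pair held identical values. The number of arrays, 3 per group, limits the precision of every comparison.

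The table held 31099 probe sets, of which 57 were manufacturer's controls and were left out of the tests. Probe sets whose mean over the 12 arrays was at or above the 40th percentile, a log2 value of 4.01, were tested, 18625 in all. A gene symbol was taken from the platform annotation and updated by Entrez identifier to the current rat gene table of assembly GRCr8, which was used for names only. Of the probe sets that are not controls, 20826 had 1 symbol, 436 had several and 9780 were unnamed here, and no name was taken from a probe set with several. Of those with 1 symbol, 20758 were matched and 68 kept the older name. A gene was represented by its passing probe set of highest mean, which gave 10606 genes. No genome of the array's build was used, so no coordinates are given.

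Each probe set was fitted with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) with 1 mean per group over all 12 arrays and no block, which leaves 8 residual degrees of freedom, with a prior of 3.68. The 5 contrasts were shunt against sham in each chamber, the difference between these 2 effects, and atrium against ventricle in sham and in shunt rats. P-values were two-sided and Benjamini-Hochberg adjusted over the probe sets tested, with a threshold of 0.05. All differences are on the log2 scale, and errors are the standard errors (SE) of the fit unless a standard deviation (SD) is named. The sources describe the pools as biological replicates, and p-values measure the spread between pools. This spread is estimated over all groups together, not within the groups compared.

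Before the data were examined, 33 gene lists for pathways and cell types were written from textbook knowledge, with 1244 different genes, of which 917 were measured. Each list was tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. Camera with an estimated correlation and limma's fry were alternatives. Fry asks whether a list's genes move, on balance, one way, and does not compare them with other genes. The rule for named genes was also fixed then. For the shunt comparisons and for atrium against ventricle in sham rats, it took the 8 largest rises and the 8 largest falls among genes past the threshold whose arrays did not overlap, filled to 5 by smallest p where fewer passed. It took up to 4 passing members of each list that passed or had at least 2 passing members, filled to 2 by smallest p. In both shunt comparisons it always took Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1 and Col3a1, and for the difference of the effects the 5 genes of smallest p in each direction. The text names part of these, and says where a gene was chosen after its values were seen.

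The alternatives were no filter, a filter at the 60th percentile, a further quantile normalization, cyclic loess, array weights, a trended and robust prior, a fit of only the groups compared, the replicate number as a block over all groups or within an operation, a minimum fold of 1.5, 1 probe set per gene, the mean of a gene's probe sets, and leaving out each array. Added after seeing the data were the 3′ minus 5′ difference of the hexokinase control probe sets as a covariate, and a fit without the 3 shunt arrays where that difference was highest. The fit was tested on simulated data for shunt against sham in left atrium, with 18625 probe sets and 200 of them changed in the simulated atrial shunt arrays. It recovered 58% of 50 probe sets changed by 0.5 on the log2 scale, 94% of 50 changed by 1, 98% of 50 changed by 1.5 and all of 50 changed by 2, with 9 other calls. The simulated spread was normal, independent between genes and, for a given probe set, equal on all arrays, which real arrays do not guarantee. In the real data the root mean square deviation from the group mean was 0.200 on atrial shunt 3, against 0.0913 to 0.110 on the atrial sham arrays. Recovery in the real comparison may therefore differ.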

Results

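Expression was measured in left atrium and left ventricle of rats 28 days after a sham operation or an aorto-caval shunt, with 3 pools per group and 12 arrays in all. Arrays of 1 group correlated at 0.983 to 0.996 across probe sets, sham and shunt arrays of 1 chamber at 0.984 to 0.991, and atrial and ventricular arrays at 0.935 to 0.950. The design asks how a volume load changes each chamber, whether the chambers differ in that response, and how they differ without it.

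In the left atrium, Thbs4, a matrix protein of loaded muscle, rose by 2.86 ± 0.40 (SE, n = 3 per group, limma adjusted p = 0.00696), and Hamp, the iron-regulating peptide hepcidin, rose by 1.97 ± 0.36 (adjusted p = 0.0249). Myh7, the slow myosin heavy chain, rose by 1.63 ± 0.18 (adjusted p = 0.00228), and Acta1, skeletal alpha-actin, rose by 1.29 ± 0.17 (adjusted p = 0.00536). H19, an imprinted non-coding RNA, fell by 2.04 (SE 0.19, adjusted p = 0.000805), and Igf2, the imprinted growth factor beside it, fell by 0.87 (SE 0.10, adjusted p = 0.00257). In all, 243 of 18625 probe sets passed, 89 higher and 154 lower, for 148 genes by their representative probe set, of which 62 were higher and 86 lower.

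Among the other large atrial changes, Ltbp2, a binding protein of the extracellular matrix, rose by 1.30, Kcnip2, a subunit of the transient outward potassium channel, by 1.33, and Sbsn by 1.21. The uncharacterised LOC102553868 rose by 1.43. Rasd1 fell by 1.95, Gpr15lg by 1.68 and Epb41l3 by 1.21. The orphan nuclear receptors Nr4a1 and Nr4a3 fell by 1.64 and 1.38, and Igfbp3, a carrier of insulin-like growth factors, fell by 1.23.

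Among markers of cardiac load, Nppb, which encodes B-type natriuretic peptide, was 0.70 ± 0.15 higher in the atrium without passing (adjusted p = 0.0513). Nppa, which encodes atrial natriuretic peptide, differed by 0.10 ± 0.28 there (limma adjusted p = 0.911), at mean log2 values of 14.15 in sham and 14.24 in shunt arrays. The highest value of any probe set on any array was 14.29. This error is estimated over all groups, and the ventricular arrays spread more widely in Nppa. The atrial arrays alone did not overlap, at 14.22 to 14.29 after the shunt and 14.11 to 14.18 in sham. The same held for 3861 of 18625 probe sets in this comparison (20.7%), so it is weak evidence of a rise. Myh6, the fast myosin heavy chain, differed by 0.01 ± 0.06, the calcium pump Atp2a2 by -0.08 ± 0.05, and the fibrillar collagens Col1a1 and Col3a1 by -0.05 ± 0.13 and 0.03 ± 0.08. None of these passed.

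**Figure D1:**
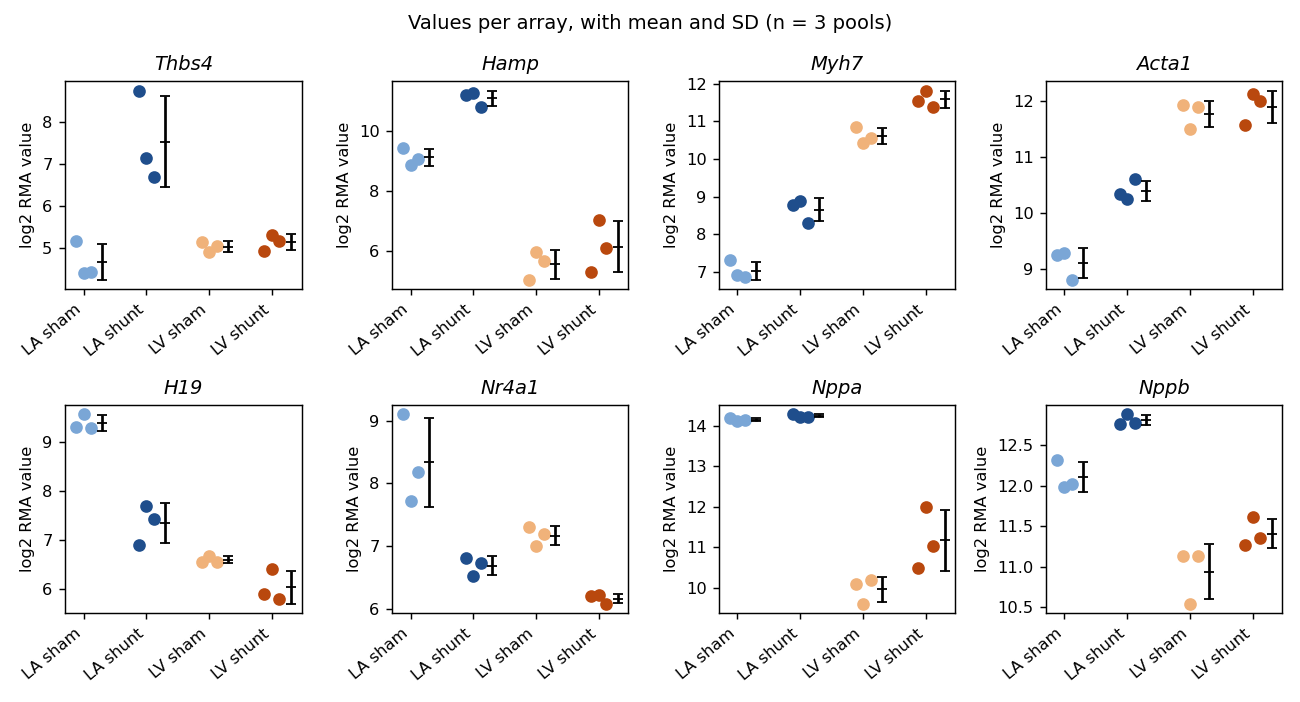
Log2 RMA values of 8 genes on each array, by chamber (LA, left atrium; LV, left ventricle) and operation, with the group mean and SD (n = 3 pools). Thbs4, Hamp, Myh7 and Acta1 lie higher and H19 and Nr4a1 lower in all 3 atrial shunt arrays than in the atrial sham arrays.

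Of the gene lists, 15 of 33 passed in the atrium by camera. The fatty acid oxidation list was lower (mean -0.18 over 44 genes, adjusted p = 5.49e-08). Of its members 2 fell and the others did not pass, with 11 lower when adjusted over the list alone. Pdk4, which restrains glucose oxidation, fell by 0.92 and Rxrg, a retinoid receptor, by 0.41, but Rxrg passed in only 1 of the 12 fits that left out 1 array (-0.50 to -0.35), where Pdk4 passed in 12. The list's call was lost with an estimated correlation (adjusted p = 0.478). The nerve and Schwann list was higher (mean 0.27 over 13 genes, adjusted p = 4.46e-05), the only one of the 15 whose call held with an estimated correlation (adjusted p = 0.0362). Of its members 2 rose, 4 when adjusted over the list alone, and 12 of 13 had a positive difference. Prph, a neuronal intermediate filament, rose by 0.90 and Cnp, an enzyme of myelinating cells, by 0.53, but Cnp passed in only 2 of the 12 fits that left out 1 array (0.43 to 0.63), where Prph passed in 12.

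The collagens and matrix list was higher (mean 0.20 over 50 genes, adjusted p = 0.00286; adjusted p = 0.728 with an estimated correlation). Of its members 4 rose, with 11 higher and 1 lower when adjusted over the list alone. They were Thbs4, Ltbp2, the basement membrane collagen Col4a2 by 0.55 and the collagen-associated Cthrc1 by 0.37. The fibroblast list passed with a mean of 0.06 (adjusted p = 0.0341; 0.728 as the adjusted p with an estimated correlation), and of its 33 genes 3 rose, with 3 higher and 1 lower when adjusted over the list alone, Meox1 by 1.12, Thy1 by 0.46 and Cthrc1. The macrophage list was higher by a mean of 0.18 over 38 genes (adjusted p = 5.99e-05; adjusted p = 0.636 with an estimated correlation), although 0 of its members passed singly over all probe sets and 2 when adjusted over the list alone. Lyz2, a lysozyme of myeloid cells, was 0.62 ± 0.15 higher without passing (adjusted p = 0.0657). In the antigen presentation list, with a mean of 0.15 over 17 genes (adjusted p = 0.0266; adjusted p = 0.636 with an estimated correlation), RT1-Da, a class II histocompatibility chain, rose by 0.62 and the chemokine receptor Cxcr4 by 0.57, with 4 higher and 1 lower when adjusted over the list alone. A probe set of another class II chain, RT1-Bb, chosen after its values were seen, was at 3.69 or less on all 6 sham arrays and differed between shunt arrays by 4.36. Without atrial shunt 3 the means of the collagens, fibroblast, macrophage and antigen presentation lists were 0.31, 0.17, 0.31 and 0.25, and without atrial shunt 1 they were 0.11, 0.02, 0.11 and 0.10. The collagen call ended without atrial shunt 1. The fibroblast call ended without atrial shunt 1, shunt 2 (mean 0.00), sham 1 (0.07) or sham 2 (0.05), and the antigen presentation call without atrial shunt 1, shunt 2 (0.11) or sham 1 (0.15). The macrophage list kept its call, at 0.11 without atrial shunt 2.

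The collagen, fibroblast, macrophage and antigen presentation lists did not move alike on the 3 atrial shunt arrays. Relative to the atrial sham mean, the macrophage list stood at 0.31, 0.32 and -0.10 on arrays 1, 2 and 3, the collagens at 0.36, 0.25 and -0.02, the fibroblast list at 0.16, 0.19 and -0.16, and antigen presentation at 0.26, 0.24 and -0.05. Fatty acid oxidation stood at -0.23, -0.22 and -0.08. The nerve and Schwann list stood at 0.24, 0.28 and 0.28. Array 3 also had the highest 3′ minus 5′ difference of the hexokinase control probe sets, a measure of how far labelling reached along a transcript, at 1.44 against at most 1.10 on the atrial sham arrays.

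**Figure D2:**
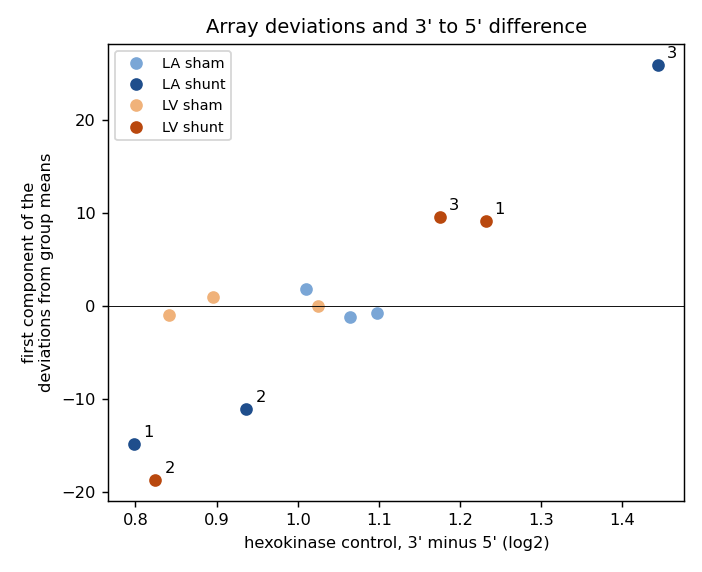
First principal component of each array's deviations from its group mean (y axis) against the 3′ minus 5′ difference of the hexokinase control probe sets (x axis, log2), 1 point per array, with shunt replicate numbers (LA, left atrium; LV, left ventricle). Atrial shunt 3 lies highest on both axes, at 1.44 and 25.9.

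**Figure D3:**
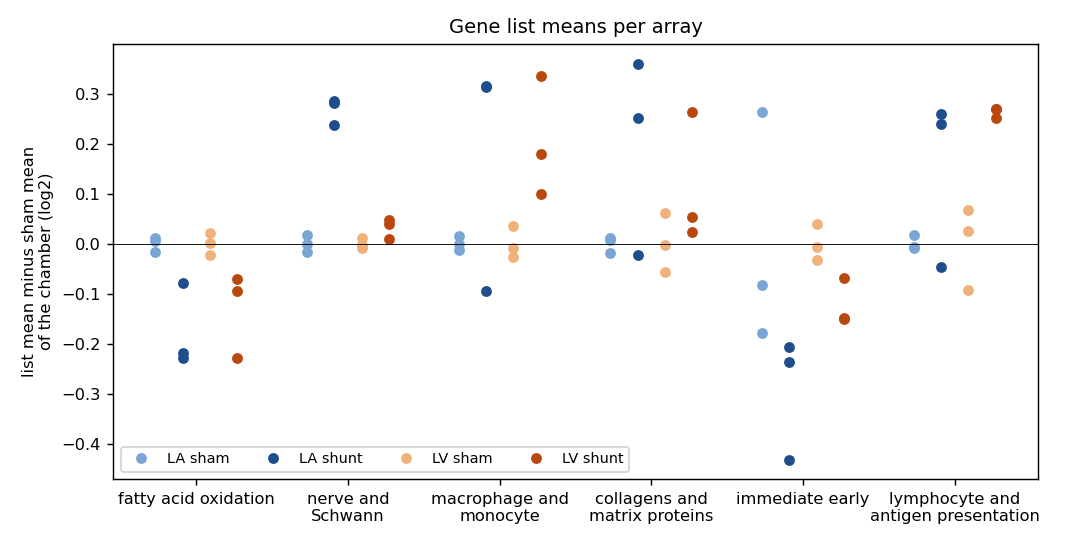
Mean log2 value of 6 gene lists on each array minus the sham mean of its chamber (LA, left atrium; LV, left ventricle); each point is 1 array. In the nerve and Schwann list the 3 atrial shunt arrays lie at 0.24 to 0.28, while in the macrophage list 1 of them lies at -0.10.

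The immediate early list, of genes induced within minutes of a stimulus, was lower (mean -0.29 over 30 genes, adjusted p = 0.00605; adjusted p = 0.636 with an estimated correlation), and Nr4a1 and Nr4a3 were its 2 members that passed, with 1 higher and 6 lower when adjusted over the list alone. Atrial sham 1 stood apart in this list, at 0.26 against -0.18 and -0.08 on sham 2 and 3 and -0.24, -0.21 and -0.43 on the shunt arrays, and the call ended without atrial sham 1 (mean -0.16) or atrial shunt 3 (-0.22). In the heat shock list (mean -0.08 over 33 genes, adjusted p = 0.0265; adjusted p = 0.636 with an estimated correlation), the chaperone Hspa1a fell by 0.57, with 1 higher and 3 lower when adjusted over the list alone, and the call ended without atrial shunt 1 (mean -0.07) or sham 1 (-0.08). The calcium handling list was lower (mean -0.11 over 38 genes, adjusted p = 0.00691; adjusted p = 0.0965 with an estimated correlation), with 0 members past the threshold. In the fetal and stress list (mean 0.22 over 20 genes, adjusted p = 0.0265; adjusted p = 0.663 with an estimated correlation), Myh7 and Acta1 rose, and 4 members when adjusted over the list alone, and the call ended without atrial sham 3 (mean 0.19). In the cytoskeleton list (mean 0.06 over 52 genes, adjusted p = 0.000548; adjusted p = 0.41 with an estimated correlation), S100a4 rose by 0.60 and the integrin-linked kinase Ilk by 0.31, while Tuba8 fell by 0.73 and Pdlim3 by 0.61, with 14 higher and 3 lower when adjusted over the list alone, and its mean was 0.03 without atrial shunt 2 and 0.09 without atrial shunt 3. The ribosome, matrix turnover, smooth muscle and apoptosis lists also passed as higher, with means of 0.05, 0.06, 0.06 and 0.05 and no member past the threshold, also when adjusted over the list alone. With an estimated correlation their adjusted p was 0.728, 0.728, 0.41 and 0.478. The ribosome call ended without atrial shunt 3 or sham 1 (mean 0.04 in each fit). The matrix turnover call ended without atrial shunt 1 (0.02), shunt 2 (0.04), sham 1 (0.06) or sham 2 (0.05), and its mean was 0.13 without atrial shunt 3. The smooth muscle call ended without atrial shunt 1 (0.04), shunt 2 (0.05) or sham 3 (0.04), and its mean was 0.09 without atrial shunt 3. The apoptosis call ended in 6 of 12 fits that left out 1 array, without atrial shunt 1 or 2, any atrial sham array or ventricular sham 3, at means of 0.04 to 0.05. On atrial shunt 3, where the hexokinase difference was 1.44, the matrix turnover, smooth muscle and cytoskeleton lists stood at -0.07, -0.01 and -0.01.

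Lists that did not pass as a whole still held single changes. In the sarcomere list 4 of 26 genes rose, Myh7, the ventricular light chain Myl3 by 1.13, Synpo2l by 0.54 and Myl9 by 0.51, with 5 higher and 1 lower when adjusted over the list alone. In the ventricular myocyte list 3 of 25 rose, Myh7, Myl3 and Kcnip2, with 6 higher and 7 lower when adjusted over the list alone. In the ion channel list 3 rose and 4 fell of 45, with 7 higher and 7 lower when adjusted over the list alone. The sodium channel subunit Scn4b fell by 1.18, and the potassium channels Kcnj12 and Kcnd2 fell by 0.80 and fell by 0.64. In the growth factor list, 3 rose and 3 fell of 48, with 8 higher and 6 lower when adjusted over the list alone, among them Ccn2, a matricellular growth factor, up by 0.98.

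Of the 38 called atrial genes that the naming rule took, 19 kept their call in each of the 12 fits that left out 1 array, and 10 kept it in every alternative in which they were tested, Myh7, Acta1, LOC102553868, H19, Igf2, Igfbp3, Rasd1, Gpr15lg, Pdk4 and Kcnd2. Of the other 9, Thbs4, Kcnip2, Ltbp2, Prph, Scn4b, Epb41l3 and Nr4a3 lost it when only the atrial arrays were fitted, and Col4a2 and Hspa1a when a change of at least 1.5-fold was asked for. Those that lost it in at least 1 fit without an array were Hamp, Sbsn, Meox1, Ccn2, Myl3, Myl9, Synpo2l, Cthrc1, Thy1, Cxcr4, RT1-Da, Cnp, Rxrg, S100a4, Ilk, Tuba8, Pdlim3, Kcnj12 and Nr4a1. With only the atrial arrays fitted, 43 probe sets passed and 14 of the 38 genes kept their call. The count of 243 fell to 66, 79 and 137 without atrial sham 3, 2 and 1, to 99 and 97 without atrial shunt 1 and 2, and to 152 and 161 without ventricular sham 1 and 3; it rose to 469 without atrial shunt 3. The count of 15 lists, which 1 other split of the 6 atrial arrays also gave, fell to 8 without atrial sham 1 and to 9 without atrial shunt 1.

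In the left ventricle, 20 probe sets passed, 11 higher and 9 lower, for 12 genes by their representative probe set; probe sets of Ogn and RT1-Bb that do not represent their gene also passed. The split turned to 16 higher and 22 lower (42.1% higher, against 55%) after a further quantile normalization and to 11 and 13 (45.8%) with cyclic loess. Vnn1, a pantetheinase, rose by 0.64 ± 0.07 (n = 3 per group, limma adjusted p = 0.0119), the sterol transporter Abcg1 by 0.72 ± 0.10 (adjusted p = 0.0353), and RT1-Da by 0.68 ± 0.11, Bex1 by 0.82 ± 0.13, Rbm3 by 0.58 ± 0.09 and Mcf2l by 0.50 ± 0.08 (adjusted p = 0.0487 for each of these 4). Wfdc1, a secreted protease inhibitor, fell by 1.24 (SE 0.16, limma adjusted p = 0.0209), and Slc24a3, a potassium-dependent sodium-calcium exchanger, fell by 0.77 (SE 0.09, limma adjusted p = 0.0119). Cacng6, a calcium channel subunit, fell by 0.70, Txn2, the mitochondrial thioredoxin, by 0.58, Tpd52l1 by 0.47 and Myh13 by 0.45. Myh13 belongs to a family of near-identical myosin genes, so its signal is uncertain.

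The load markers did not pass in the ventricle. Nppa was 1.20 ± 0.28 higher (adjusted p = 0.105), with log2 values of 10.48, 11.99 and 11.04 on shunt arrays 1, 2 and 3 against 10.11, 9.61 and 10.19 on the sham arrays. Myh7 was 0.98 ± 0.18 higher (adjusted p = 0.0672), Nppb 0.47 ± 0.15 (adjusted p = 0.21) and Acta1 0.13 ± 0.17 (adjusted p = 0.782). Myh6, Atp2a2, Col1a1 and Col3a1 differed by -0.03, -0.03, 0.00 and 0.03.

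By camera 10 of 33 lists passed in the ventricle, and 0 held with an estimated correlation. Fatty acid oxidation was lower (mean -0.13 over 44 genes, adjusted p = 6.09e-06; adjusted p = 0.627 with an estimated correlation), with 0 members past the threshold, 2 when adjusted over the list alone, and 38 of 44 below 0. Its members of smallest p were Ucp2, an inner-membrane carrier, at -0.56 ± 0.10 and Pdk4 at -0.42 ± 0.08, and its mean was -0.08 without ventricular shunt 2. The macrophage list was higher by a mean of 0.20 (adjusted p = 6.09e-06; adjusted p = 0.737 with an estimated correlation), with 0 of 38 members past the threshold; the chemokine Ccl2 was 0.55 ± 0.14 higher. Antigen presentation was higher by 0.26 over 17 genes (adjusted p = 5.3e-05; adjusted p = 0.601 with an estimated correlation), where RT1-Da rose and 6 members passed when adjusted over the list alone. It stood at 0.27, 0.27 and 0.25 on the 3 ventricular shunt arrays, while the macrophage list stood at 0.10, 0.33 and 0.18, the collagens at 0.02, 0.26 and 0.05 and fatty acid oxidation at -0.09, -0.23 and -0.07. The hexokinase 3′ minus 5′ difference was 1.23, 0.82 and 1.18 on those arrays, against at most 1.02 on the ventricular sham arrays.

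The other ventricular lists were collagens (mean 0.11, adjusted p = 0.00116), heat shock (-0.09, adjusted p = 0.00184), ribosome (0.05, adjusted p = 0.0191), endothelial (0.08, adjusted p = 0.0243), matrix turnover (0.08, adjusted p = 0.027), immediate early (mean -0.12, adjusted p = 0.0343) and calcium handling (-0.07, adjusted p = 0.0409), all with 0 members past the threshold. Adjusted over the list alone, 3 heat shock genes were lower and 1 ribosome gene higher. On ventricular shunt 1, 2 and 3 the ribosome list stood at 0.07, -0.01 and 0.10, heat shock at -0.13, -0.03 and -0.10, immediate early at -0.15, -0.07 and -0.15 and matrix turnover at 0.04, 0.17 and 0.04, and the hexokinase difference was highest on arrays 1 and 3. Without arrays 1 and 3 and atrial shunt 3, the ribosome mean turned to -0.0089. With an estimated correlation their adjusted p was 0.737, 0.601, 0.737, 0.601, 0.737, 0.737 and 0.601. Without ventricular shunt 2 the collagen, matrix turnover and endothelial calls ended (means 0.04, 0.04 and 0.08) and the ribosome mean was 0.09. Without ventricular sham 2 the matrix turnover, endothelial, calcium handling, immediate early and ribosome calls ended (0.07, 0.07, -0.07, -0.14 and 0.04). The calcium handling, immediate early and ribosome calls also ended without ventricular shunt 1 (-0.06, -0.11 and 0.04) or shunt 3 (-0.08, -0.11 and 0.03), and the immediate early call without ventricular sham 3 (-0.10). Each of the 12 called genes lost its call in at least 1 fit that left out 1 array, and 4 of them, Slc24a3, Wfdc1, Cacng6 and RT1-Da, kept it when only the ventricular arrays were fitted, where 10 probe sets passed. The count of 20 fell to 0 without ventricular sham 1, ventricular sham 3 or ventricular shunt 3, to 5 without ventricular shunt 1, to 9 without ventricular sham 2, and to 7, 6, 5 and 12 without atrial sham 1, 2 and 3 and atrial shunt 2. It rose to 45 without ventricular shunt 2 and to 118 without atrial shunt 3, which enters only through the shared spread. The count of 10 lists fell to 5 without ventricular sham 2.

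The shunt effects of the chambers were related across probe sets (r = 0.529, rho = 0.436 over 18625 probe sets, which are not independent replicates), and the comparisons share no array. They may still share rats, which the labels do not say. Of the 6 pairs of an atrial and a ventricular array with 1 number and operation, 4 had deviations correlated above 0.1 (range -0.24 to 0.44). The effects of the chambers may therefore not be independent. Of the 243 atrial calls, 208 had the same sign in the ventricle (85.6%, against 64.7% of all probe sets). Calls in both chambers numbered 4 higher and 3 lower, where independent lists would share 0.0526 and 0.0744. Both comparisons used the same estimate of spread per probe set, so this is not the value without a shared effect, and fits on each chamber's own arrays shared 1 call among 43 atrial and 10 ventricular ones. The 7 calls were of RT1-Da, Mcf2l and the matrix proteoglycan Ogn (0.72 and 0.55 in the atrium and 1.02 and 0.96 in the ventricle on its 2 probe sets) upward, and Slc24a3, Wfdc1 and Tpd52l1 downward.

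**Figure D4:**
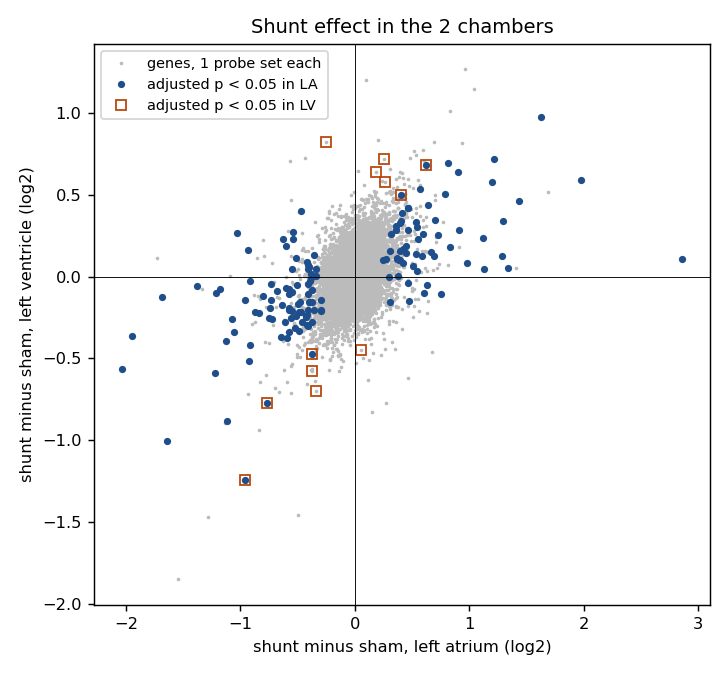
Shunt minus sham difference in left atrium (x axis, log2) against left ventricle (y axis, log2), 1 probe set per gene; filled points passed in the atrium and open squares in the ventricle. Wfdc1, Slc24a3, Tpd52l1, RT1-Da and Mcf2l passed in both, and Thbs4, at 2.86 in the atrium, lies farthest to the right.

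No probe set passed limma's test of the difference between the effects (0 of 18625, smallest adjusted p = 0.0854), with 1229 (6.60%) at an unadjusted p under 0.05. On average a share of 0.05 would be reached with no difference in any probe set. The smallest p belonged to Gpr15lg, with an atrial minus ventricular effect of -1.56 ± 0.20, and to Klhl40 (-0.87 ± 0.12), Rasd1 (-1.58 ± 0.24), Slc7a7 (-1.02 ± 0.17) and Amot (-0.82 ± 0.14). In the other direction stood Myot, a Z-disc protein (1.08 ± 0.19), LOC102553868 (0.97 ± 0.18), Taok3 (0.49 ± 0.09), Myh13 (0.51 ± 0.10) and S100a4 (0.70 ± 0.14). None of these 10 passed. Gpr15lg stood at 3.42 to 3.85 on every ventricular array, below the filter's 4.01, where signal and background were not separated. A ventricular fall could not be seen there, so its difference between the effects is uncertain. Myot was also below 4.01 on the ventricular shunt arrays, at 3.72 to 3.91, and on atrial sham 2, at 3.779. On atrial sham 1 and 3 Myot stood at 4.104 and 4.078. Rasd1 stood at 3.997 to 4.908 in the ventricle, below 4.01 only on ventricular shunt 2. A ventricular fall of Rasd1 from such low values could be understated, so its difference between the effects is also uncertain. Amot, Slc7a7 and Taok3 lay little above 4.01 in the ventricle, at 4.08 to 4.79. The count of probe sets past the threshold was 19 without atrial shunt 3 and 1 without atrial sham 1, atrial shunt 2 or ventricular shunt 2. Of 33 lists, nerve and Schwann passed (mean difference 0.24 over 13 genes, adjusted p = 0.000682), with Npy, a sympathetic transmitter, furthest apart at 0.61 ± 0.13 and past the threshold only when adjusted over the list alone. With an estimated correlation its adjusted p was 0.0654.

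Between the chambers of sham rats, 8782 probe sets passed, 4690 higher in atrium and 4092 higher in ventricle, 1043 of them at least 2-fold apart. The majority turned after a further quantile normalization, from 53.4% higher in atrium to 46.4%. Higher in atrium than in ventricle were the atrial light chains Myl4 (8.06 ± 0.13, n = 3 per group, limma adjusted p = 5.45e-12) and Myl7 (6.72 ± 0.52), the calcium pump inhibitor sarcolipin, Sln (8.02 ± 0.18), and Mybphl (6.92), Atp1b4 (5.67), Epha4 (5.26), Vsnl1 (4.94) and Obp3 (4.84). Nppa was 4.18 ± 0.28 higher, with atrial values near the top of the range. In ventricular sham arrays Atp1b4, Obp3 and Vsnl1 had means of 2.41, 3.02 and 3.03, below the filter's 4.01, where signal and background were not separated. Differences against such low values, or from values near the top of the range, can understate a change. The naming rule took the largest rises and falls by these same differences, so the order of the genes is uncertain. Higher in ventricle were the light chains Myl2 (-9.10 ± 0.19 as atrium minus ventricle) and Myl3 (-5.72 ± 0.21), the ribosomal protein Rpl3l (-5.61), the opioid precursor Penk (-5.39), the glycerol channel Aqp7 (-4.59), Gpsm1 (-4.28), the chemokine Cxcl11 (-4.26) and the transcription factors Irx3 (-4.24) and Irx4 (-4.14), of which Irx3 and Irx4 had atrial means of 3.31 and 3.39.

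Of the markers of atrial myocytes 16 of 21 were higher and 4 lower (adjusted p = 3.7e-07; adjusted p = 0.174 with an estimated correlation), and of those of ventricular myocytes 15 of 25 were lower and 3 higher (adjusted p = 1.22e-06; adjusted p = 0.0616 with an estimated correlation). Over all 10606 genes tested, 2922 passed as higher in atrium and 2397 as lower, and the list counts are to be read against this. From glycolysis on, the counts below give only members that moved with their list. Energy metabolism lists were lower in the atrium. Of 85 genes of the citric acid cycle and oxidative phosphorylation, 65 were lower and 1 higher (adjusted p = 3.47e-15; adjusted p = 0.174 with an estimated correlation), with 68 lower when adjusted over the list alone, Cox7a1 by -2.52 and Idh3b by -0.78, and of 44 of fatty acid oxidation 35 were lower and 3 higher (adjusted p = 1.08e-12; adjusted p = 0.174 with an estimated correlation), Acaa2 by -1.93 and Acadm by -1.77. Glycolysis was lower with 17 of 31 (adjusted p = 0.00246; adjusted p = 0.194 with an estimated correlation). Mesothelial markers, of the cell layer that covers the heart, were higher for 14 of 17 (adjusted p = 8.42e-05; adjusted p = 0.208 with an estimated correlation), Upk1b by 4.13 over a ventricular mean of 3.23 and Msln by 3.95. Fibroblast genes were higher for 21 of 33 (adjusted p = 8.42e-05; adjusted p = 0.37 with an estimated correlation), and collagens and matrix for 26 of 50 (adjusted p = 0.000375; adjusted p = 0.567 with an estimated correlation), among them Efemp1 by 2.12 and Fn1 by 1.80. Antigen presentation was lower for 12 of 17 (adjusted p = 2.52e-05; adjusted p = 0.174 with an estimated correlation), Cxcl9 by -1.62 and Cd74 by -1.08, and ribosome and translation higher for 27 of 32 (adjusted p = 4.64e-06; adjusted p = 0.357 with an estimated correlation), Rpl3 by 1.52. Growth factor signalling was higher for 29 of 48 genes and heat shock for 20 of 33, and smooth muscle was lower for 13 of 23; with an estimated correlation their adjusted p was 0.37, 0.39 and 0.174. By camera 17 of 33 lists passed and 0 held with an estimated correlation, where the lowest adjusted p was 0.0616, for ventricular myocyte markers.

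Among ion channel genes the atrium was higher in Kcnj5 (2.98) and Kcnj3 (2.32), which form the acetylcholine-gated potassium channel, and lower in Kcnip2 (-3.97) and Scn4b (-3.06). In shunt rats 7801 probe sets differed between the chambers, 4179 higher in atrium and 3622 higher in ventricle, and quantile normalization turned this majority from 53.6% higher in atrium to 47.6%. Of all, 6481 passed in both operations with the same sign and 2 with opposite signs.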

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

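Apart from the comparison of the chambers' effects, the counts over other splits of the arrays, and the test of the axis against the shunt effect, the tests in this part were chosen after the result was seen. The nerve and Schwann list differed between the chambers in its shunt effect (mean difference 0.24 on the log2 scale, atrium minus ventricle), by limma's camera on the interaction. The list was at 0.24 to 0.28 above sham on the 3 atrial shunt arrays and at 0.01 to 0.05 on the ventricular ones. Its call held in all 12 fits that left out 1 array and was lost with an estimated correlation. It counts among 1 list passing, against up to 14 in other regroupings of the arrays, and 96 of the 100 regroupings drawn gave as many, so chance is not excluded for the number of lists.

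The control probe sets, which no comparison used, showed a 3′ minus 5′ difference on some shunt arrays above the highest sham array of the chamber. For hexokinase it was 1.44 on atrial shunt 3, 1.23 on ventricular shunt 1 and 1.18 on ventricular shunt 3. For actin it was 1.34, 1.17 and 1.02 on the same arrays and 1.08 on ventricular shunt 2. For GAPDH it was 0.427 on atrial shunt 3, 0.392 on ventricular shunt 1 and 0.387 on ventricular shunt 2.

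The shunt arrays also split along 1 axis. The first component of the deviations from group means held 41.0% of their variance and stood at 25.9 on atrial shunt 3 and at 9.13 and 9.53 on ventricular shunt 1 and 3, against -14.8, -11.1 and -18.7 on the other shunt arrays and -1.15 to 1.88 on sham arrays. Over the 12 arrays it went with the within-group hexokinase difference (r = 0.954, exact permutation p = 0.0394; rho = 0.825, exact permutation p = 0.0633; r = 0.892 without the 2 arrays farthest out), but the adjusted p over the 3 controls was 0.118. Actin (r = 0.629, exact permutation p = 0.267) and GAPDH (r = 0.637, exact permutation p = 0.262) did not pass. Without the 2 arrays farthest out for each, r was 0.122 for actin and 0.025 for GAPDH. A wrong chamber label is argued against, since the lowest atrial array lay 7.65 above the highest ventricular one for Sln. RNA integrity (adjusted exact permutation p = 0.118) and a stronger response to the shunt in some pools (r = 0.257 across probe sets between the axis and the mean shunt effect, where 0.5 or more was asked for and under 0.2 would have argued against it) both stay open and may act together.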

How the results depend on the processing

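The covariate and the fit without 3 arrays were chosen after seeing the data; every other alternative was planned. The cause of a move was not tested unless named. The atrial count of 243 became 910 with array weights, 426 with a trended and robust prior, 43 with only the groups compared, 99 at 1.5-fold or more, 758 with the 3′ to 5′ covariate and 642 without the 3 shunt arrays of highest 3′ to 5′ difference, with 243 and 209 of the original calls among the last 2. The ventricular count of 20 became 82 with the stricter filter (fewer probe sets tested), 38 after a further quantile normalization, 160 with array weights, 96 with the trended prior, 10 with only the groups compared, 13 at 1.5-fold, 12 over 1 probe set per gene, 215 with the covariate and 45 without the 3 arrays, which leaves 1 ventricular shunt array assumed to vary like the other groups. Quantile normalization turned its split from 11 higher and 9 lower to 16 and 22, and cyclic loess to 45.8% higher. Quantile normalization also turned the share higher in atrium from 53.4% to 46.4% in sham and from 53.6% to 47.6% in shunt rats. The count of 0 for the difference of effects became 11, 1, 1, 2, 1 and 15 with array weights, the trended prior, 1 probe set per gene, the mean of probe sets, the covariate and without the 3 arrays. Atrium against ventricle gave 2832, 5394 and 5505 in sham and 2656, 4924 and 4991 in shunt rats at 1.5-fold, over 1 probe set per gene and over the mean of probe sets, where fewer units are tested or a size is asked. Lists passing fell with an estimated correlation from 15, 10, 1 and 17 to 1, 0, 0 and 0 (atrium, ventricle, difference, chambers in sham), and were 2, 1 and 27 by fry in atrium, ventricle and chambers. For the difference, 1 list became 4 with the stricter filter, 7 with array weights, 5 with the covariate and 2 without the 3 arrays. Leaving out 1 array gave 66 to 469 in atrium, 0 to 118 in ventricle, 0 to 19 for the difference, 7340 to 9346 and 6666 to 7957 between chambers in sham and shunt, and 8 to 16, 5 to 11, 1 to 9 and 16 to 17 lists. The ribosome list turned to -0.0089 in the ventricle without the 3 arrays. The macrophage list for the difference ranged from -0.0956 to 0.11 over the fits without 1 array. It passed in opposite directions, at 0.11 without left atrium shunt replicate 3 and at -0.12 with the covariate. Fry gave ion channels (mean 0.0235) and lung (mean 0.21) between the chambers the direction opposite to camera's. Of the called named genes, 19 of 38 in atrium, 0 of 12 in ventricle and 122 of 129 between chambers in sham kept their call in each fit without 1 array, 10, 0 and 109 kept it in every alternative that tested them, and 14, 4 and 129 with only the groups compared. The labels do not say whether arrays of the same number share rats, so the number was not taken as a pairing in the main fit. Of the 18 pairs of arrays with 1 number, 4 had deviations correlated above 0.1 (-0.24 to 0.44). All 4 were among the 6 pairs within an operation, and the other pairs set sham against shunt rats and cannot bear on shared rats. Of the 12 arrays, 9 correlated best with their own number. Shared rats are therefore not excluded. With the replicate block the counts were 208, 15, 0, 8818 and 7825, with 29 of 38 named atrial and 7 of 12 named ventricular calls among them. With the replicate block within operation they were 253, 10, 0, 9009 and 8057, with 38 of 38 and 5 of 12 such calls and 2 lists for the difference. Signals near background limit what low probe sets can show.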

Other observations

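The tests on RT1-Bb and on ventricle-high genes in this part were chosen after the values were seen; the counts over other splits were planned. Other class II histocompatibility genes than RT1-Da had positive differences in the ventricle after the shunt. RT1-DMb was 0.77 ± 0.17 higher (limma adjusted p = 0.092), RT1-Ba 0.74 ± 0.16 (adjusted p = 0.0818) and RT1-Db1 0.77 ± 0.23 (adjusted p = 0.175), none past the threshold, while their chaperone Cd74 differed by 0.12 ± 0.09; apart from RT1-Ba these genes were chosen after their values were seen. Clec3b, which encodes tetranectin and was chosen after its values were seen, loaded second most strongly on the axis that split the shunt arrays (loadings of -0.0983 and -0.0617 on its 2 probe sets).

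1 of the 2 probe sets of RT1-Bb, chosen after its values were seen, was near background on all 6 sham arrays (at most 3.69) and reached 8.03 in the shunt arrays, 5 of 6 of which lay above every sham array. In the ventricle it was 3.74 ± 0.60 higher (limma adjusted p = 0.0487). More transcript of the whole gene is argued against, since the other probe set differed by 0.00 ± 0.27 with an upper 95% limit of 0.601, and more antigen-presenting cells as the whole cause are argued against, since the largest change among the other class II genes and Cd74 was 0.774. An allele detected by 1 probe set may differ between pools, and the range of 4.36 over the shunt arrays, from 3.68 to 8.03, leaves this open because the genotypes of the rats are not known. If sham and shunt rats differ in genotype here, this also bears on RT1-Da.

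Of the 62 genes that rose in the atrium, 7 were at least 2-fold higher in ventricle than in atrium among shunt arrays, Acta1, Myl3, Myh7, Kcnip2, LOC102553868, Asap2 and Itsn2, or 11.3% against 2.18% of genes tested. Of the 86 that fell, 11 were so (12.8%), and taken among sham arrays the counts were 8 rising and 6 falling genes (12.9% and 6.98%, against 2.08% of genes tested). These shares were not tested against each other, and each measure shares an atrial group with the change. Ventricular tissue in the atrial shunt samples is argued against as the whole cause: the 7 rises would need a median share of 17.6%, which would raise the 10 genes with the largest ventricular over atrial difference in sham rats, Myl3 and Kcnip2 among them, by a median of 2.21, and their median change was -0.0816 (SD 0.733 over the genes), with Myl2 at 0.71 ± 0.19 against 6.61 at that share. Myl3 needed the smallest share of the 7, at 2.28%. That share of the ventricular sham level would by itself exceed the atrial shunt levels of Myl2, Rpl3l and Penk (5.24, 4.29 and 4.95). Their ventricular sham levels were 13.63, 10.50 and 10.57, and the other genes set no such bound. A share of that size is therefore argued against. A still smaller share is not excluded, and a change of the myocytes under load stays a hypothesis. RNA integrity as a cause of the 7 rises could not be tested well. The hexokinase 3′ minus 5′ difference was 0.80 and 0.94 on atrial shunt 1 and 2 and 1.44 on shunt 3, against 1.01 to 1.10 in atrial sham. It thus lay on both sides of sham. All 7 genes were higher on each atrial shunt array than on any atrial sham array. The sham and shunt arrays of all 243 atrial calls did not overlap, however, so this followed from the selection and is no test. The atrial group means of the hexokinase difference were 0.00258 apart, so a shift in proportion to it would hardly move the group means. For the same reason the covariate, under which 7 of 7 genes passed, had little to remove. An effect of integrity that is not in proportion to this control, or that it does not measure, stays open.

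Splits of 3 arrays against 3 number 10, too few for a share under 0.05. The real atrial split gave 243 probe sets and the highest other 0, the ventricular one 20 and 1, the chambers in sham 8782 and 0, and the chambers in shunt 7801 and 645, each with 1 of 10 splits as large as the real one. For gene lists the real and highest other counts were 15 and 15 in atrium (2 of 10 splits as large), 10 and 7 in ventricle and 17 and 16 between the chambers in sham, so camera with a preset correlation also called many lists in splits that mix the operations or chambers. For the difference of the effects the real count was 0, which each of the 100 regroupings drawn from 200 reaches by construction, so these say nothing about chance. The highest other was 894. That regrouping exchanged sham and shunt in all ventricular arrays and in no atrial one, so by construction it tested the sum of the chambers' shunt effects, and the next highest count was 8.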
